A study of Mus musculus with 5 samples.

How the data were processed

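Total RNA from whole mouse testes at postnatal day 9 was measured on 5 single-colour Cy3 NimbleGen expression arrays of the MM8 60mer design, per the labels' protocols. RNA was extracted with TRIzol, cleaned on RNeasy MinElute columns and checked on a Bioanalyzer, per the labels. The deposited values are linear-scale intensity values, 1 per transcript identifier and array, and RMA is the tool named in the submitters' processing notes, with no version given. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of a transcript, so a shift of total RNA between samples cannot be seen in such values and small differences of dim transcripts are compressed. How many probes stand behind each value and where they lie on the transcript is not given in the sources used here.

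From the deposited intensities, log2 values were taken, with no further normalization, no pseudocount and no filter on dim transcripts. The table held 25631 rows, and median intensities lay between 721 and 730 on the 5 arrays. Row identifiers were matched without versions to a RefSeq gene table of assembly GRCm38.p6, used for names only, since the array was designed on another build and no coordinates are reported. Of all rows, 17777 matched 1 symbol, none matched several and 7854 stayed unnamed, most of them predicted transcripts, of which 19 of 6752 were named. The named rows covered 17274 distinct symbols. Where a gene had several rows, the row with the highest mean over all arrays stood for it. For Fn3k the rows disagreed, since its other, dimmer row differed by 0.39 between the NGN-cre knockout and the control against 2.19 for the row used.

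The labels gave 3 arrays of Dmrt1 knockout with NGN-cre, 1 Cre-negative control array carrying the NGN-cre label, and 1 array of Dmrt1 knockout with DHH-cre. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. The array numbers in the labels place the DHH-cre array apart from the other 4, so array batch and the DHH-cre group cannot be told apart. The number of arrays limits the precision of every value. The 1060 olfactory receptor transcripts had a median log2 intensity of 5.23, and where one side of a difference lies near or below that level the size of the fold is uncertain.

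Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), with 1 mean per group over all 5 arrays. The 2 residual degrees of freedom came from the 3 NGN-cre knockout arrays alone, and the lone control and DHH-cre arrays were assumed to vary like them. A permutation of 3 arrays against 1 cannot give a p below 0.25. The DHH-cre array against the control was 1 array against 1, so no test was made: a transcript was counted when the difference was at least 2-fold and larger than the range of the 3 NGN-cre arrays for the same transcript. The same size rule was applied to the NGN-cre knockout only after the test results had been seen.

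A set of 19 gene lists with 276 members, covering germ cell stages, somatic testis cells, possible tissue carried over, sex-linked genes and stress, was written before the data were examined, and 251 members were measured. Lists were tested with camera in limma with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. For the DHH-cre array against the control, each list's median was placed among the medians of 10000 random lists of the same size matched on mean expression. Random lists drew genes independently, so wherever they are used their range is too narrow for genes that vary together. The genes named follow a rule also set before the data were examined: Dmrt1, then the 10 largest rises and falls among named genes past the threshold, or, where fewer passed, the next by moderated statistic up to 5, and for each list up to 4 members past the threshold or the 2 largest differences. Cloned cDNA names and predicted genes were counted but not named. Lists of oocyte genes and of duct epithelium genes were added after the values had been seen.

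Tests were run on simulated data of 25631 rows. Each row was drawn independently, and every array was given the spread estimated from the NGN-cre knockout arrays. For the NGN-cre knockout against the control, 0 of 50 transcripts changed by 1 log2 unit were recovered, 39 of 50 changed by 2, 48 of 50 changed by 3 and 50 of 50 changed by 4, with 9 false calls. For the DHH-cre against the NGN-cre knockout the counts were 1, 37, 48 and 49 of 50, with 5 false calls. A simulated list shifted by a fixed amount was called by camera with the preset correlation, while with an estimated correlation it was missed in both comparisons, at an adjusted p = 0.408 and an adjusted p = 0.323. Fry, by direction, called it for the NGN-cre knockout against the control (adjusted p = 0.0158) and missed it between the knockouts (adjusted p = 0.118). Genes of the simulated list varied independently, whereas the estimated correlation in the data was 0.528 for the meiotic prophase list. The simulation therefore does not show how often the preset correlation gives false calls on correlated lists. Alternatives covered leaving out each NGN-cre array, 3 other normalizations and filters on the dimmest 30% and 50% of rows. They also covered other variance models, other thresholds and averaging the rows of a gene. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.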

Results

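Dmrt1 encodes a transcription factor with a DM domain that is made in germ cells and Sertoli cells of the mouse testis. The series compared gene expression in juvenile testes in which Dmrt1 had been conditionally deleted with that in control testes, at postnatal day 9. The labels name the deleter strains only as NGN-cre and DHH-cre. In the mouse, Neurog3 is transcribed in spermatogonia and Dhh in Sertoli cells, but the labels do not say whether the driver names refer to these genes. Whole testes were profiled on 5 arrays, 3 from NGN-cre knockouts, 1 from a Cre-negative control and 1 from a DHH-cre knockout. Pearson correlations across log2 values were 0.989 to 0.993 among the NGN-cre knockout arrays, 0.986 to 0.990 between these and the control, and 0.975 to 0.981 between the DHH-cre array and the others. At most 7 of 25631 values were identical between any pair of arrays.

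The targeted gene was lower than the control in every knockout array. Dmrt1 had an intensity of 11847 in the control, 5346 ± 406 (SD, n = 3) in the NGN-cre knockouts and 6416 in the DHH-cre knockout. The NGN-cre knockout level was 45.0% of the control, a log2 difference of -1.15 (SE 0.22), which did not pass the threshold over all transcripts (limma, Benjamini-Hochberg adjusted p = 0.281). With an intensity trend in the variance model it did (limma, Benjamini-Hochberg adjusted p = 0.0368), and over all alternatives the adjusted p ran from 0.0368 to 0.666. The DHH-cre knockout level was 54.2% of the control, and the knockouts differed by 0.27 (SE 0.22; limma, Benjamini-Hochberg adjusted p = 0.576). The deposited values do not show whether the probes lie in the deleted part of the gene, and cells in which a driver is inactive keep the transcript.

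The first comparison asked how testes with the NGN-cre deletion differed from the control. Measured against the spread between arrays, the clearest differences were higher values in the knockout of Tbx19, a T-box transcription factor known from the pituitary, and of Crabp2, a cellular retinoic acid binding protein. Tbx19 was 20.7-fold higher (log2 4.37, SE 0.40) and Crabp2 6.43-fold higher (log2 2.69, SE 0.22), and each was above the control in 3 of 3 arrays. Neither passed the threshold (limma, Benjamini-Hochberg adjusted p = 0.118 for both). Ap3b2, a subunit of the neuronal AP-3 adaptor complex, differed by 2.85, the fructosamine kinase gene Fn3k by 2.19 and the cytochrome P450 gene Cyp2e1 by 2.05. In the opposite direction, the T-box gene Tbx1 differed by -1.96, the zinc finger gene Sp6 by -1.95 and the cerebellin gene Cbln2 by -1.81. Mpped1 differed by -1.65 and the olfactory receptor gene Olfr1264 by -1.41. The NGN-cre mean of Olfr1264 lay below 5.23, the median log2 intensity of olfactory receptor transcripts, and the control value of Tbx19 (5.74) lay near it. The sizes of these differences are therefore uncertain.

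Of 25631 transcripts, limma called 0 at a Benjamini-Hochberg adjusted p under 0.05, the smallest being 0.118. At an unadjusted p under 0.05 there were 2015, with 1191 higher and 824 lower in the knockout. The count rested on NGN-cre replicate 3: without it 238 transcripts passed, 190 higher and 48 lower, and so did each of the 10 genes named above. With an intensity trend in the variance model 66 passed, 55 higher and 11 lower. By the size rule, applied after the test results had been seen, 481 transcripts were at least 2-fold apart, 341 higher and 140 lower in the knockout, and without NGN-cre replicate 3 there were 826. Leaving out replicate 3 takes the spread from replicates 1 and 2, the most alike pair of arrays (SD of differences 0.35), and may understate it. Replicate 3 lay about as far from the control (SD of differences 0.41) as from replicate 2 (0.44).

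**Figure D1:**
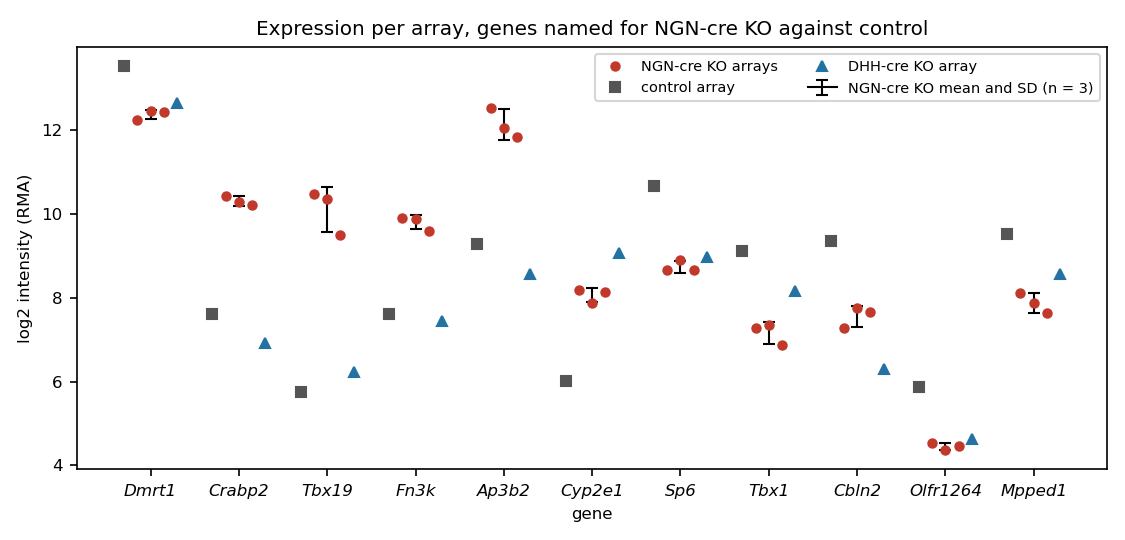
Log2 intensity (vertical axis) of Dmrt1 and of the 10 genes named for the NGN-cre knockout against the control, with 1 point per array and black bars for the mean and SD of the 3 NGN-cre knockout arrays. Dmrt1 lies at 13.5 in the control and at 12.4 ± 0.11 in the NGN-cre knockouts, and Crabp2, Tbx19, Fn3k and Ap3b2 lie higher in each NGN-cre knockout array than in the control and DHH-cre arrays.

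Among the gene lists, germ cell lists moved apart in the NGN-cre knockout. The meiotic prophase list, of synaptonemal complex and recombination genes, was shifted up, with a median log2 difference of 0.54 and 17 of 18 measured members higher (camera in limma with the preset correlation, Benjamini-Hochberg adjusted p = 1.7e-07; adjusted p = 0.539 with an estimated correlation). Its largest members were Dmrtc2, a germ cell DM-domain gene, 2.82-fold higher, and the recombinase gene Dmc1 at a log2 difference of 1.27. The list of undifferentiated spermatogonia was shifted down, with a median of -0.45 and 16 of 19 members lower (adjusted p = 0.000312, and adjusted p = 0.539 with an estimated correlation). Without NGN-cre replicate 3 this median was -0.29. Pax7 stood at -1.14, while Cdh1, which encodes the epithelial adhesion protein E-cadherin, went against the list at 1.30. The pan-germ cell list was shifted up by a median of 0.21 with 13 of 14 members higher (adjusted p = 0.0029, and adjusted p = 0.539 with an estimated correlation), among them Tex101 at 1.01 and Rnf17 at 0.74. No member of any list passed over all transcripts. Adjusted over the list alone, 5 meiotic and 2 undifferentiated members passed and 0 pan-germ cell members did.

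Lists of other cell types moved as well, and with each the adjusted p = 0.539 with an estimated correlation, so no call held there. The macrophage list was shifted up, with a median of 0.44 and 10 of 11 members higher (camera in limma with the preset correlation, Benjamini-Hochberg adjusted p = 0.000135), including Adgre1 at 1.20 and the receptor gene Csf1r at 0.86. The Sertoli cell list was shifted down, with a median of -0.33 and 18 of 21 members lower (adjusted p = 0.00194), including the follicle-stimulating hormone receptor gene Fshr at -0.71. The pluripotency list was shifted up by a median of 0.22 with 8 of 11 members higher (adjusted p = 0.0123), led by Dppa3 at 2.04 and Dppa5a at 1.38, but its median was below the control in NGN-cre replicate 3, at -0.13, and was 0.44 without that array. The Y-linked list was shifted up by 0.33 with 5 of 8 members higher (adjusted p = 0.0456), led by the similar genes Zfy2 at 1.76 and Zfy1 at 0.81, whose probes may not tell them apart. The Y-linked call was lost in 6 of 11 alternatives, among them leaving out NGN-cre replicate 1 (camera in limma, adjusted p = 0.0747) and repeating quantile normalization (adjusted p = 0.0514), over a range of adjusted p from 0.00776 to 0.539. Adjusted over the list alone, 3 pluripotency members passed and 0 macrophage, Sertoli cell and Y-linked members did.

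The remaining lists were not called in this comparison. Their medians were 0.12 for differentiating spermatogonia, where Stra8 stood at 0.83 and Sohlh2 at 0.39, -0.20 for post-meiotic spermatids, 0.17 for endothelial cells, 0.10 for granulosa and ovarian somatic cells, -0.03 for Leydig cells and 0.08 for peritubular myoid cells and stroma. Cell cycle genes had a median of 0.04, immediate early and heat shock genes -0.18, retinoid pathway genes -0.08, p53 targets -0.04, erythroid genes 0.02 and epididymis genes -0.09. In the last 4 the mean had the opposite sign to the median, at 0.03, 0.05, -0.12 and 0.16, and camera followed the sign of the mean except for the retinoid pathway. In 5 of these lists the 2 largest differences, none past the threshold, went opposite ways. They were 2.69 for Crabp2 and -0.76 for Stra6 in the retinoid list, 1.09 for Spaca1 and -0.86 for Acr, both of the acrosome, in the post-meiotic list, and -1.05 for Lrp8 and 1.01 for Nr5a2 in the granulosa list. They were 0.80 for Cdkn1a and -0.32 for Trp53inp1 among p53 targets, and -0.59 for Star and 0.41 for Hsd3b6 among Leydig cell genes. The epididymis list held Crisp1, a secreted protein of the epididymis, at 1.94 and Adam7 at 0.46. In the endothelial list Emcn stood at 0.64 and Pecam1 at 0.51, in the peritubular list Tagln at 0.55 and Des at 0.28, in the cell cycle list Top2a at 0.63 and Bub1 at 0.53, and in the immediate early list Jun at -0.53 and Dusp1 at -0.43. Genes of duct epithelium, a tissue that can be carried over with the testis, were high in the NGN-cre knockout, with a median of 0.36, 11 of 15 higher and percentile 99.9 of random lists of like expression. That list was written after the values had been seen.

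**Figure D2:**
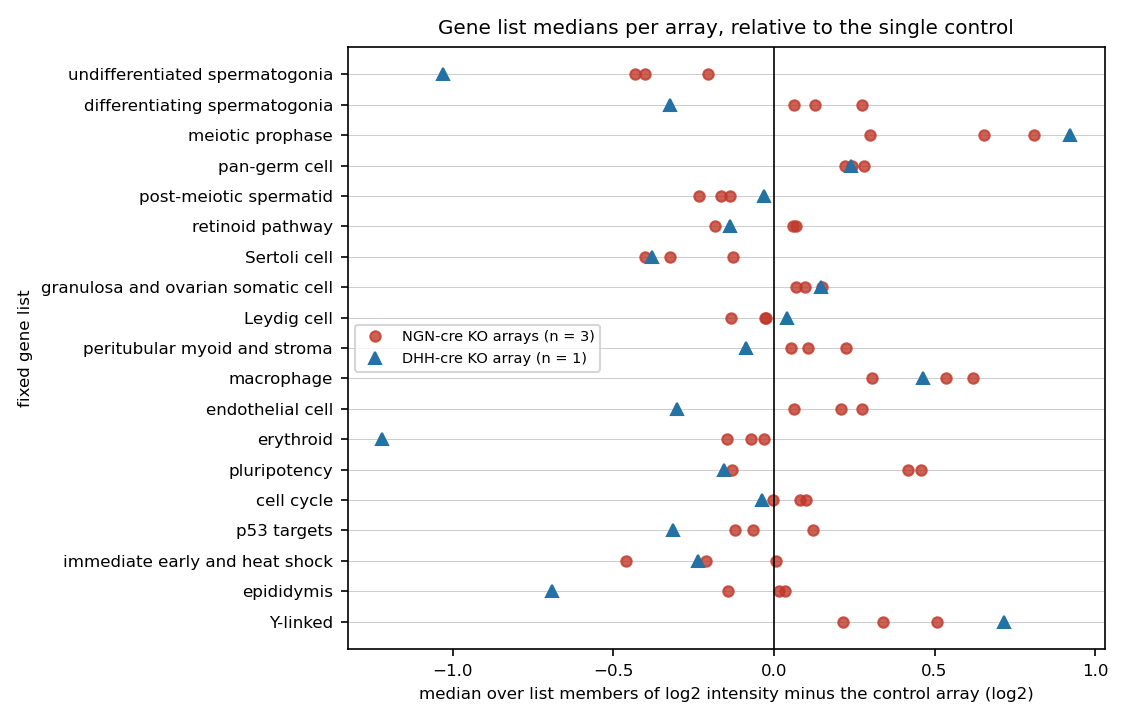
Median log2 difference from the single control array (horizontal axis) of each of the 19 gene lists, for each NGN-cre knockout array (circles, n = 3) and for the DHH-cre knockout array (triangle, n = 1). The meiotic prophase list lies above 0 in all 4 knockout arrays, from 0.30 to 0.92, and the list of undifferentiated spermatogonia below 0, from -0.20 to -1.03.

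The second comparison set the DHH-cre knockout array against the same control, with no replicate on either side. Serpina3n, a serine protease inhibitor gene, was 90.7-fold higher in the knockout, and the Golgi protein gene Tmem87a 21.9-fold. Also among the 10 largest were the olfactory receptor gene Olfr39 at 4.40, Zfy2 at 4.24, Gml2 at 4.15, Kctd19 at 3.80, Arl9 and Pdcl2 at 3.75, Glipr1l2 at 3.49 and the sperm surface protein gene Adam2 at 3.46. The tight junction gene Ocln was 32.0-fold lower (log2 -5.00) and the retinol transporter gene Stra6 20.6-fold lower (log2 -4.37). Further low values were -4.89 for Rnf138rt1, a retrotransposed copy of Rnf138, -4.54 for Atp13a4, -4.41 for Etd, -4.26 for Jakmip1, -4.20 for Plac1, -4.05 for Cytip, -4.04 for Crisp1 and -3.99 for Sh3gl2.

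By the size rule 2654 transcripts were apart, 1422 higher and 1232 lower in the DHH-cre knockout. At least 2-fold apart from the control with no condition on the range were 2752 transcripts on the DHH-cre array, against 819, 1293 and 662 on the 3 NGN-cre arrays. This difference has no replicate check, and array batch and group cannot be told apart. The control value of Olfr39 and the DHH-cre values of Etd and Crisp1 lay below 5.23, the median log2 intensity of olfactory receptor transcripts. The control values of Adam2 (5.293) and Pdcl2 (5.636) and the DHH-cre value of Cytip (5.289) lay near it. The size of all these differences is therefore uncertain.

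In the DHH-cre array the meiotic, undifferentiated and Sertoli cell lists lay on the same side of the control as in the NGN-cre knockouts. The median of differentiating spermatogonia was below the control, at -0.325, but inside the central range of random lists (-0.343 to 0.331). The only member of that list counted by the size rule, Stra8, was higher, at 1.01. The meiotic prophase list had a median of 0.92 with 17 of 18 members higher and 9 counted by the size rule, including Msh5 at 2.51, Spo11 at 2.36, Dmrtc2 at 2.26 and Msh4 at 2.15. The list of undifferentiated spermatogonia had a median of -1.03 with 17 of 19 lower and 10 counted, including Tspan8 at -2.29, Neurog3 at -1.95, Sall4 at -1.72 and Ret at -1.58. The Sertoli cell list had a median of -0.38 with 19 of 21 lower and 4 counted, which were Cst9 at -3.56, Fshr at -2.27, Defb19 at -1.49 and Sox8 at -1.08. Foxl2, a transcription factor of ovarian granulosa cells, was 4.21-fold higher (log2 2.07). Also counted in the granulosa and ovarian somatic cell list were Oosp1 at 1.26, Lrp8 at -1.42 and Inhba at -1.07. Of these, Oosp1 is also on the list of oocyte genes. That list as a whole had a median of 0.145 with 10 of 18 higher.

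Among 10000 random lists of like expression, 8 lists lay outside the central 95%. The random lists drew genes independently, so this range is too narrow for lists whose genes vary together. Besides the meiotic, undifferentiated and Sertoli cell lists, Y-linked genes (0.715), macrophage genes (0.46) and pan-germ cell genes (0.24) lay high. Erythroid genes (-1.22) and epididymis genes (-0.69) lay low. All 6 measured erythroid genes were lower, including Slc4a1 at -1.60, and Crisp1 was the only epididymis gene counted. Stra6 and Lrat (-1.43) were counted in the retinoid list, Pou5f1 (-2.38) and Utf1 (-1.07) in the pluripotency list, and Hsd17b3 (-3.29) and Hsd3b6 (1.96) in the Leydig cell list. The post-meiotic spermatid list lay inside the random range, with a median of -0.03 and 10 of 16 lower, as did the genes of duct epithelium, with a median of -0.19 and 13 of 15 lower.

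The third comparison set the DHH-cre knockout array directly against the 3 NGN-cre knockout arrays, without the control. Crisp1 was lower in the DHH-cre knockout (log2 -5.98, SE 0.22; limma, Benjamini-Hochberg adjusted p = 0.00104), and Ocln 20.3-fold lower (log2 -4.34, SE 0.23; limma, Benjamini-Hochberg adjusted p = 0.0035). Also lower were Padi6, a peptidylarginine deiminase of oocytes, at -4.61, the sodium channel subunit gene Scn4b at -4.10, the protease inhibitor gene Spink8 at -4.04, Tbx19 at -3.88, Rnf138rt1 at -3.84, Atp13a4 at -3.77, Jakmip1 at -3.75 and Stra6 at -3.60. Higher in the DHH-cre knockout were Tmem87a at 5.02 (SE 0.48), Serpina3n at 4.76, Olfr39 at 3.35 and the sperm protein genes Adam2 at 3.17, Adam18 at 2.92 and Crisp2 at 2.68, as were Morc2b at 3.08, Tbr1 at 2.51, Hoatz at 2.43 and Lpcat2b at 2.38. Each of these 20 genes passed the threshold. The DHH-cre values of Crisp1 and Scn4b and the NGN-cre mean of Tbr1 lay below 5.23, the median log2 intensity of olfactory receptor transcripts. The NGN-cre means of Hoatz (5.365), Lpcat2b (5.505) and Adam2 (5.582) lay near it. The size of all these differences is therefore uncertain.

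In all, limma called 257 transcripts at a Benjamini-Hochberg adjusted p under 0.05, 70 higher and 187 lower in the DHH-cre knockout, 160 of them named. Without NGN-cre replicate 1 there were 38 and without NGN-cre replicate 3 there were 1321, and with an intensity trend in the variance model 729. Of the 20 named genes, Serpina3n, Olfr39, Adam2, Adam18, Tbr1, Hoatz, Rnf138rt1, Atp13a4 and Stra6 no longer passed without NGN-cre replicate 1, at adjusted p from 0.0524 to 0.0894 (limma, Benjamini-Hochberg). Array batch and group cannot be told apart here either. The test also assumes that the DHH-cre array varies like the NGN-cre arrays. Over olfactory receptor transcripts the SD of differences averaged 0.512 against the DHH-cre array and 0.369 among the other 4. The SE and adjusted p of this comparison may therefore be too small, and its calls too many.

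Spermatogonial and meiotic lists moved apart between the deletions as well. In the DHH-cre knockout the list of undifferentiated spermatogonia was shifted down by a median of -0.63, with 17 of 19 members lower (camera in limma with the preset correlation, Benjamini-Hochberg adjusted p = 7.45e-05; adjusted p = 0.459 with an estimated correlation). Of its members 2 passed over all transcripts, Cdh1 at -1.99 and Tspan8 at -1.62. The meiotic prophase list was shifted up by 0.37, with 18 of 18 members higher (adjusted p = 0.000174, and adjusted p = 0.508 with an estimated correlation), the largest being Msh4 at 1.69 and Msh5 at 1.54. The Y-linked list was shifted up by 0.54 with 8 of 8 members higher (adjusted p = 0.000949, and adjusted p = 0.459 with an estimated correlation). No meiotic or Y-linked member passed over all transcripts. Adjusted over the list alone, 8, 2 and 3 members of these lists passed.

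Other lists were shifted down in the DHH-cre knockout, and with an estimated correlation each of them had an adjusted p = 0.501, or an adjusted p = 0.459 for the erythroid and Sertoli cell lists. Pluripotency genes had a median of -0.75 with 8 of 11 lower (camera in limma with the preset correlation, Benjamini-Hochberg adjusted p = 0.00608), and Pou5f1 at -3.18 and Dppa3 at -1.88 passed over all transcripts. Erythroid genes had a median of -1.07 with 6 of 6 lower (adjusted p = 7.45e-05), and Slc4a1, the red cell anion exchanger, passed at -1.60. Sertoli cell genes had a median of -0.32 with 14 of 21 lower (adjusted p = 0.00699), and Cst9 at -3.06 and Fshr at -1.55 passed, but without NGN-cre replicate 1 the median was -0.14. Epididymis genes had a median of -0.53 with 7 of 10 lower (adjusted p = 0.0115), and of these Crisp1 passed. Genes of duct epithelium, listed after the values had been seen, were low beside them, with a median of -0.58 and 13 of 15 lower. Endothelial genes had a median of -0.48 with 7 of 8 lower and 0 past the threshold (adjusted p = 0.0174). Retinoid pathway genes had a median of -0.16 with 13 of 19 lower (adjusted p = 0.0373), and Stra6 and Crabp2 (-3.39) passed, but the list call was lost without NGN-cre replicate 2 (adjusted p = 0.0673). Adjusted over the list alone, 5 pluripotency, 5 erythroid, 4 Sertoli cell, 3 epididymis, 0 endothelial and 3 retinoid members passed. In lists that were not called, Hsd17b3 (-3.27), Hsd3b6 (1.55), Nr5a2 (-1.48) and Cdkn1a (-1.88) passed as single genes. The granulosa and ovarian somatic cell list was not called, and its median of -0.125 and mean of 0.074 differed in sign.

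The differences of both knockouts from the shared control correlated across transcripts, with a Pearson correlation of 0.577. Unchanged groups simulated against the same control gave 0.612 on average, from 0.602 to 0.626 over 100 simulations. The simulations gave every array the NGN-cre spread, which largely fixes this value. Over olfactory receptor transcripts the DHH-cre array scattered more (SD of differences 0.512, against 0.369 among the other 4). More scatter in that array would lower the simulated correlation, so the comparison does not decide whether 0.577 exceeds what a shared control gives. Genes are not independent replicates. The covariance was 0.149 against 0.0555 in the simulations, a difference of 0.0937. By the size rule 217 transcripts were higher in both knockouts, against 11.2 in the simulations and 18.9 for independent lists, and 89 were lower in both, against 10.5 and 6.73. The simulated counts rest on the same NGN-cre spread, and the figures for independent lists leave out the shared control. Both references may therefore be too low. The control could not be split, so some or all of the excess may come from it. In opposite directions by the size rule were 4 transcripts, higher in the NGN-cre and lower in the DHH-cre knockout, named here after their values were seen: Crisp1 (1.94 and -4.04), Spink8 (2.85 and -1.19), Eddm3b (1.30 and -1.50) and Cldn8 (1.07 and -1.41). Crisp1, Spink8 and Eddm3b are known from the epididymis.

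**Figure D3:**
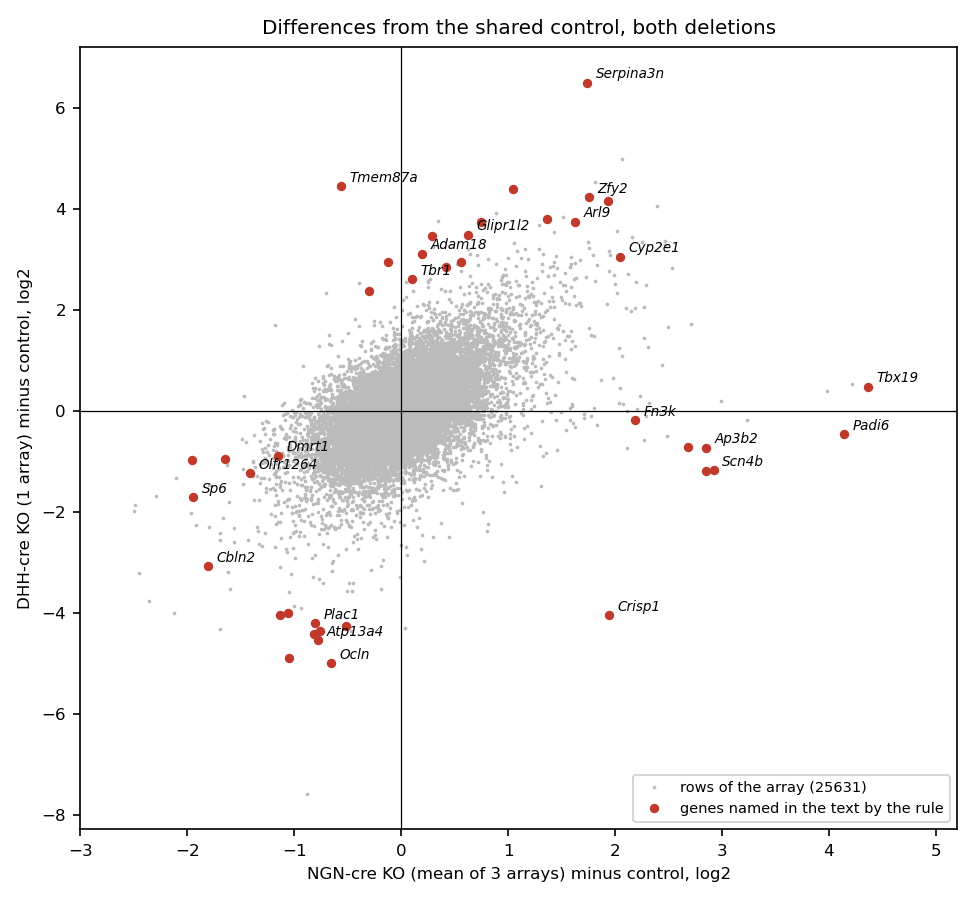
Log2 difference from the control in the DHH-cre knockout (vertical axis, 1 array) against that in the NGN-cre knockouts (horizontal axis, mean of 3 arrays) for 25631 transcripts (grey) and the genes named by the rule (red; labels are given where there is room). Crisp1 lies at 1.94 and -4.04, and Dmrt1 at -1.15 and -0.88.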

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

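The tests on duct epithelium, on the share of germ cells and on the stage of the control were chosen after the result had been seen. A number of genes and lists differed between the deletions by limma's test of the DHH-cre against the NGN-cre knockout, in which array batch and group cannot be told apart. Among the genes and list members named for the NGN-cre comparison, the difference was -3.58 for Ap3b2, -1.99 for Cdh1, -1.88 for Cdkn1a, -3.39 for Crabp2, -5.98 for Crisp1, -1.88 for Dppa3, -2.36 for Fn3k, -1.55 for Fshr, 1.55 for Hsd3b6, -1.48 for Nr5a2, -3.60 for Stra6 and -3.88 for Tbx19. Among the lists the median difference was -0.63 for undifferentiated spermatogonia, 0.37 for meiotic prophase, -0.16 for the retinoid pathway, -0.32 for Sertoli cells, -0.48 for endothelial cells, -1.07 for erythroid genes, -0.75 for pluripotency genes, -0.53 for epididymis genes and 0.54 for Y-linked genes. No list call held with an estimated correlation.

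The DHH-cre array stood apart from the other 4. Over 1060 olfactory receptor transcripts, with a median log2 intensity of 5.23, the SD of differences was 1.39 times as large against the DHH-cre array as among the others, against 1.46 for all transcripts, a value between the bounds of 1.1 and 1.5 set in advance, and array batch cannot be told apart from the group. Unequal amounts of epididymal duct tissue may add to the distance from the NGN-cre arrays: 15 measured genes of duct epithelium, a list that leaves out the 4 genes that prompted it but whose values were seen before the test was set, had a median of -0.58 against those arrays, at percentile 0.01 of random lists. Against the control the list was high in the NGN-cre knockouts (0.36, percentile 99.9) and not unusual in the DHH-cre array (-0.19, percentile 14.1), while the epididymis list, fixed beforehand, was low in the DHH-cre array (-0.69, percentile 0.05) and not unusual in the NGN-cre knockouts (-0.09, percentile 24.7), so the lists place the difference in different arrays and leave the distance from the control open. Lcn5 and Rnase9 of the epididymis list and Pate4 of the duct list lay near or below 5.23 in every array, so these members say little about duct tissue. None of the 15 duct genes passed on its own, and the brightest, Epcam (-0.19) and Esrp1 (-0.18), which germ cells also express, differed little. Duct tissue would not raise the 70 transcripts called higher in the DHH-cre knockout, and a response to the DHH-cre deletion also stays open.

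In the NGN-cre knockouts the meiotic list was high and the list of undifferentiated spermatogonia low. A larger share of germ cells with an unchanged mix of stages would move both lists the same way. They lay apart by 0.934 (SD 0.248, n = 3) and in opposite directions in all 3 arrays. This argues against a larger share with an unchanged mix as the whole cause. All 3 gaps are measured from the same control array, so the SD covers only the spread between knockout arrays. A larger share of germ cells stays open as a part, and so does a larger share in which the mix of stages also differs. The pan-germ cell list was high (0.21) and the Sertoli cell list low (-0.33), each in all 3 arrays. A control testis at an earlier point of the first wave of spermatogenesis cannot be told apart from an effect of the deletion, since every knockout array lay on the same side of the 1 control, the nearest by 0.734 and the DHH-cre array by 1.95. An effect of losing Dmrt1 remains an open hypothesis.

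For the NGN-cre knockout against the control, 2015 transcripts lay at an unadjusted p under 0.05 with the control as the lone array, and at most 1691 with an NGN-cre array in its place. For the DHH-cre against the NGN-cre knockout, 257 passed the adjusted threshold with the DHH-cre array as the lone array and at most 0 otherwise. In each case the real arrangement was 1 of 4, and 4 arrangements are too few for a share under 0.05.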

How the results depend on the processing

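No paired analysis was possible because the control and the DHH-cre knockout have 1 array each, and slide as a block was not run because each array has a slide number of its own. The size rule for the NGN-cre knockout was chosen after seeing the data. No result reversed, and the cause of the moves below was not tested, except that filters and looser thresholds change what is counted by construction. Leaving out each NGN-cre array in turn gave 0 to 238 called transcripts for the NGN-cre knockout against the control (0 in full), 38 to 1321 for the DHH-cre against the NGN-cre knockout (257 in full), 458 to 826 by the NGN-cre size rule (481 in full) and a correlation of the differences from 0.540 to 0.567 (0.577 in full). With an intensity trend, limma called 66 and 729 transcripts, and Dmrt1 passed at -1.15 (limma, Benjamini-Hochberg adjusted p = 0.0368). At an adjusted p under 0.1, 1061 passed between the knockouts. Without the dimmest 50% of rows the size rules gave 997 (DHH-cre, 2654 in full) and 196 (NGN-cre) and the correlation was 0.650, or 0.597 without the dimmest 30%. At 1.5-fold the size rules gave 6469 and 1884. With an estimated correlation camera called 0 lists in either comparison with a test, and fry called 0 by direction in each, and 3 against the control and 12 between the knockouts in either direction of change (7 and 9 lists with the preset correlation). Over single genes, 189 of 198 alternatives left the call in place between the knockouts and 9 ended it, and against the control 84 of 100 left it and 16 brought a gene past the threshold. Over single lists, 59 of 77 alternatives left the call in place against the control and 18 ended it. Between the knockouts 78 of 98 left it and 20 ended it. The median of the pluripotency list in the NGN-cre knockout against the control ran from 0.209 to 0.799 over the alternatives. Signal over background per probe was not used here, so what dim signals limit is unknown.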

Other observations

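Oocyte genes stood out in the NGN-cre knockouts, a group with no list of its own beforehand, and the list and both tests were set after the values had been seen. Of its members, Gdf9, Oosp1 and Zp3 were also on the granulosa and ovarian somatic cell list and Dppa3 on the pluripotency list. Of 25 genes, 18 were higher than in the control, with a median log2 difference of 0.634, at percentile 100 of 10000 random lists of like expression (camera in limma p = 3.87e-08 with the preset and p = 0.175 with an estimated correlation). The 8 that were at least 2-fold higher were Padi6 (4.14), the zona pellucida gene Zp2 (3.98), Nlrp5 (3.24), the oocyte transcription factor gene Nobox (2.71), Dppa3 (2.04), Oas1d (1.36), Figla (1.18) and Ooep (1.06), and none passed over all transcripts. The other 17 had a median of 0.13, with Gdf9 at -0.13, Bmp15 at 0.14, Npm2 at -0.20 and Zp3 at 0.63. Bmp15 and Oog1 lay near or below 5.23, the median log2 intensity of olfactory receptor transcripts, in every array. These 2 members therefore say little about oocyte RNA. The control values of Zp2 (5.52) and Oas1d (5.25) lay near that level too, so the size of their differences is uncertain.

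A quirk of the single control array would leave the DHH-cre array as high as the NGN-cre arrays. Against the control, the 8 genes had a median of 0.253 in the DHH-cre array. The highest of them was Nobox at 1.73 and the lowest Ooep at -0.50. The 8 genes had a median difference of -1.72 between the DHH-cre and NGN-cre knockouts, but they were chosen for high NGN-cre values, and over all 25 it was -0.671, with 15 lower in the DHH-cre array than in every NGN-cre array (camera in limma p = 9.56e-05 with the preset and p = 0.281 with an estimated correlation), and with 1 DHH-cre array a quirk of the control stays open. Oocyte or ovarian RNA would raise oocyte transcripts as a set, and the median of 0.634 over all 25 (SD 1.29 over genes) does not decide. The granulosa and ovarian somatic cell list was not called, with a median of 0.10, 11 members higher and 7 lower. Its largest differences were -1.05 for Lrp8 and 1.01 for Nr5a2, and Foxl2 stood at 0.15 and Fst at 0.05. Oocyte RNA and ovarian RNA therefore both stay open. A first version of this test, on 9 genes sorted as abundant after their values had been seen, gave a median of 0.14, and it is set aside because that sorting left out Zp2, Nlrp5 and Padi6. An effect of losing Dmrt1 stays open as an untested hypothesis, and no value assigns these transcripts to a cell type.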
